A study of Mus musculus with 16 samples.

How the data were processed

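Gene expression was measured by RNA sequencing in macrophages grown from mouse bone marrow. Marrow cells were kept for 7 days with 20 ng/mL of M-CSF, the growth factor that drives macrophage differentiation, and then cultured for 24 h without or with 70% medium conditioned by YUMM1.7, a mouse melanoma cell line (tumor-conditioned medium, TCM). The 16 libraries fall into 5 groups by their genotype label, which are wild type without TCM (WT naive, n = 3), wild type with TCM (WT TCM, n = 3), TRAP1 knockout with TCM (TRAP1 KO TCM, n = 4), wild type of the JMJD3 line with TCM (JMJD3 WT TCM, n = 3) and JMJD3 conditional knockout with TCM (JMJD3 cKO TCM, n = 3). Replicate numbers were taken from the titles. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

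Per the labels' protocols, ribosomal RNA was removed with a Ribo-Zero kit, libraries were made with a TruSeq Stranded kit and sequenced on an Illumina HiSeq. The submitters' processing notes name HISAT, StringTie, Bowtie2, RSEM and the mouse build mm10, with no version and no role for any of them. The tool that made the gene values, the annotation release, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table per library with a count for each of 54532 Ensembl gene identifiers. All values were whole numbers with different totals, 15361604 to 22426820 per library, and were used as raw counts with no rounding. Symbols, positions and biotypes came from the GENCODE M21 annotation of the same build (GRCm38, also called mm10), which held 54495 of the identifiers. The 37 identifiers without a symbol took at most 0.0036% of a library's counts. Of the identifiers with a symbol, 111 shared it with a more abundant one and were kept under their identifier. Because the assignment of reads shared by near-identical genes, and the strand setting, are not known, values of genes with processed pseudogenes or overlapping antisense partners are uncertain.

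Counts were tested with edgeR (4.0.16) in R (4.3.3), with TMM scaling, filterByExpr at its default minimum of 10 counts, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. WT TCM against WT naive and TRAP1 KO TCM against WT TCM came from 1 fit of their 10 libraries (7 residual degrees of freedom). JMJD3 cKO TCM against JMJD3 WT TCM came from a fit of its own 6 libraries (4 residual degrees of freedom). JMJD3 WT TCM against WT TCM, and the difference between the genotype effects, came from 1 fit of all 16 libraries (11 residual degrees of freedom). Values in CPM (counts scaled to a common library total) are mean ± SD over the libraries of a group on TMM-scaled totals. Values of the 2 targeted genes, of the plot of 8 genes by library, of the marker sums and of the comparison of the wild-type sets use the scaling over all 16 libraries, and values of the 3 main comparisons use the scaling of their own fit, so the same group can differ slightly between them. A fold change is a log2 ratio of the test group over the control group, and its SE is that of the fitted coefficient.

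The 23 gene lists and 12 marker lists of cell types, sex and stress, the designs and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma (3.58.1) on log2 CPM with a prior count of 2 and the preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The alternatives were camera with a correlation estimated per list and the rotation test fry, which tests a list against no change and not against the other genes. Lists with fewer than 3 tested members were not tested. Named genes were, for each of the 3 main comparisons, Trap1 and Kdm6b, then the 5 called genes with the largest change in each direction among those with a mean of at least 5 CPM and groups that did not overlap, leaving out predicted and unnamed loci, then up to 3 called members of a list with the smallest adjusted p, and then a few markers of macrophage state fixed in advance (Arg1, Nos2, Il10, Cd274, Mrc1, Vegfa, Timd4 and Ppargc1a). Genes given as called in both of a pair of comparisons were the 5 per pair of directions with the largest smaller change. A few genes that these rules select are not reported here. Any other gene was named after its values were seen. Such genes were exceptions to a count, members of a list of known function or neighbours of a targeted gene. The predicted gene Gm8730 was named for its large change.

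Overlaps of the effects used Fisher's exact test, one-sided, and Pearson correlations across genes, which are not independent replicates. WT TCM is the treated group of 1 comparison and the control of another, so 20 sets of unchanged libraries were simulated for that pair. Precision at low values was limited by depth. An upper limit for a gene at 0 counts was set at 3 counts, which is 0.134 to 0.195 CPM per library. Intervals of count ratios are exact 95% intervals of a ratio of Poisson rates. Limits and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

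Library pairs within a group were compared with a chi-square test over genes with at least 20 counts. The statistic per degree of freedom lay between 1.737 and 2.724 in all 18 pairs, so no pair differed by counting noise alone. All libraries were kept as replicates, although this does not settle whether they came from separate animals or cultures. The tests were tested on simulated data with 50 genes changed at each of 4 fold sizes, all drawn from genes with a mean of at least 5 CPM. At 1.5-fold, 98% of changed genes were called for WT TCM against WT naive, 98% for TRAP1 KO TCM against WT TCM, 96% for JMJD3 cKO TCM against JMJD3 WT TCM, 96% for the wild-type sets and 88% for the difference of effects. At 1.25-fold these shares were 84%, 88%, 82%, 80% and 74%. Of all calls in these simulations, 6.3%, 5%, 7.2%, 6.4% and 6.3% were false. In the data 35.1% to 61.3% of the genes tested were called, far more than changed in the simulations, and genes under 5 CPM were tested too. The simulated shares therefore do not carry over to the data or to genes of lower level.

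The alternatives tried were DESeq2 (1.42.0) size factors or upper quartile scaling in place of TMM, the DESeq2 Wald test and limma-voom, other count filters, stricter thresholds, other sets of libraries in the fit, the replicate number as a block, each library left out in turn, lists without the targeted gene, and genes outside the chromosome windows described with the TRAP1 comparison. Tables were joined with Python (3.11.15), numpy (2.4.6), pandas (2.3.3) and scipy (1.17.1), and plots were drawn with matplotlib (3.10.9). The protocol text also mentions cells stimulated with IL-4 or with LPS and interferon gamma, and libraries of such cells were not analysed here.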

Results

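RNA was sequenced from 16 libraries of mouse bone marrow-derived macrophages in 5 groups. Wild-type cells were measured without tumor-conditioned medium (WT naive, n = 3) and with it (WT TCM, n = 3), beside TRAP1 knockout cells with it (TRAP1 KO TCM, n = 4). A second set held wild-type (n = 3) and conditional knockout (n = 3) cells of the JMJD3 line, both with TCM. TRAP1 is a mitochondrial chaperone of the HSP90 family, and JMJD3, the product of Kdm6b, removes methyl groups from lysine 27 of histone H3. Totals were 20506820 to 22351578 counts per library in WT naive, 15361604 to 19326128 in WT TCM, 17845920 to 20228057 in TRAP1 KO TCM, 15815651 to 17544225 in JMJD3 WT TCM and 19511053 to 22426820 in JMJD3 cKO TCM. Mitochondrially encoded genes took 1.16%, 1.26%, 1.43%, 0.77% and 0.84% of the counts in these groups, in the same order. The first principal component held 50.7% of the variance and placed the JMJD3 line at 37.6 to 61.5 and the other libraries at -51.0 to -6.11. Values are mean ± SD in CPM (counts scaled to a common library total), with n = 3 per group and n = 4 for TRAP1 KO TCM.

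Trap1 (ENSMUSG00000005981, chromosome 16, 4039971 to 4077827, minus strand, GRCm38) was at 68.0 ± 0.761 CPM in WT naive, 67.7 ± 5.52 in WT TCM, 0.0377 ± 0.0252 in TRAP1 KO TCM, 49.7 ± 1.64 in JMJD3 WT TCM and 57.6 ± 0.355 in JMJD3 cKO TCM. The 4 knockout libraries held 3 Trap1 counts together, and WT TCM was 1761 times higher, with an exact 95% interval of the count ratio of 602 to 8545. Dnase1, a nuclease gene whose annotated end overlaps that of Trap1, had 0 counts in the knockout against 62 in WT TCM, at least 30.2-fold lower with 3 counts over the group as the limit. Trap1 did not differ detectably between WT TCM and WT naive (log2 fold change -0.01, SE 0.05, adjusted p = 0.91). Kdm6b (ENSMUSG00000018476, chromosome 11, 69398508 to 69413675, minus strand) was at 4.82 ± 0.203 CPM in WT naive, 11.1 ± 2.16 in WT TCM, 17.1 ± 0.367 in TRAP1 KO TCM, 25.1 ± 1.69 in JMJD3 WT TCM and 25.6 ± 1.02 in JMJD3 cKO TCM. Its transcript rose with TCM (log2 fold change 1.21, SE 0.12, adjusted p = 5.8e-16) and again without TRAP1 (0.63, adjusted p = 8.4e-09). In the libraries labelled JMJD3 cKO it was not lower than in their controls (log2 fold change 0.04, SE 0.07, 95% interval -0.16 to 0.23, adjusted p = 0.75). Which exons the conditional allele removes is not given in the sources used here, and a count over the whole gene does not check a deletion of part of it. Xist, the transcript of the inactive X chromosome, was at 845 CPM in JMJD3 WT TCM and 919 CPM in JMJD3 cKO TCM, with 0 counts in WT TCM. The Y-linked gene Ddx3y was at 85.2, 86.5 and 87.2 CPM in WT naive, WT TCM and TRAP1 KO TCM, with 0 counts in the JMJD3 line. The line and the sex of the cells cannot be told apart, and each genotype is compared within its own set.

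**Figure D1:**
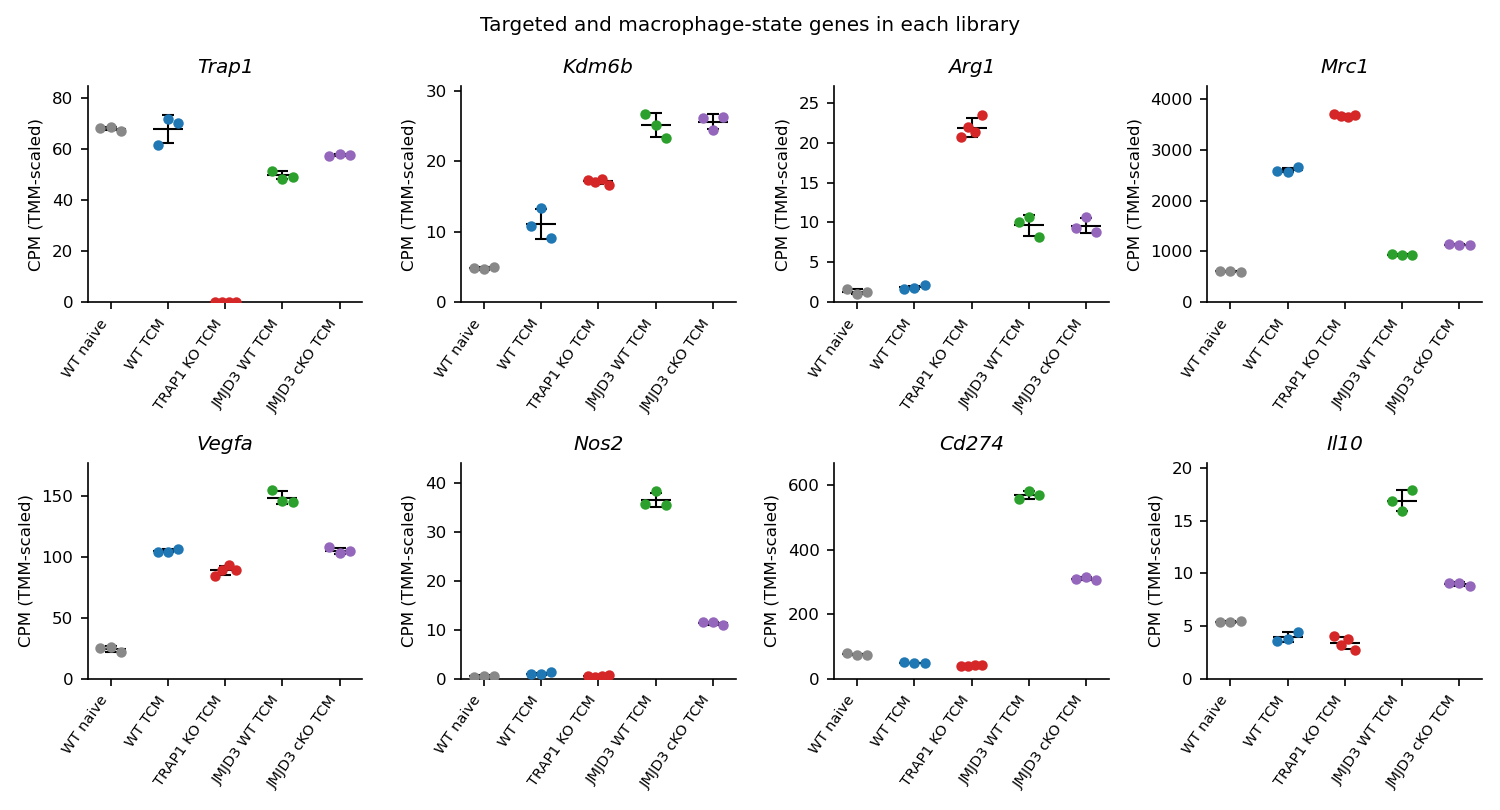
CPM per library (points, 5 groups on the x axis) of Trap1, Kdm6b, Arg1, Mrc1, Vegfa, Nos2, Cd274 and Il10, with mean and SD as bars. Arg1 lay at 21.9 CPM in TRAP1 KO TCM against 1.84 in WT TCM, and Cd274 at 311 in JMJD3 cKO TCM against 570 in JMJD3 WT TCM.

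WT TCM was compared with WT naive to see what medium from melanoma cells did to macrophages. Mrc1 (chromosome 2, 14229392 to 14332057), the mannose receptor of alternatively activated macrophages, rose from 627 ± 7.44 to 2691 ± 45.5 CPM (log2 fold change 2.10, SE 0.01, adjusted p = 9.9e-101). Vegfa, the main angiogenic growth factor, rose from 25.1 ± 2.21 to 109 ± 1.37 CPM (log2 fold change 2.11, adjusted p = 6.0e-59), together with most genes of glycolysis. Genes induced by interferon fell, and so did Cd74, the invariant chain of MHC class II, from 262 ± 3.73 to 111 ± 3.54 CPM. In all, 3040 genes rose and 2898 fell among 14078 tested, 339 and 403 of them at least 2-fold, and the median absolute log2 fold change of the called genes was 0.299.

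Among named genes with a mean of at least 5 CPM, the strongest rises were those of F13a1, the coagulation factor XIII A chain of macrophages, from 3.85 ± 0.246 to 93.9 ± 1.88 CPM (log2 fold change 4.61), and Clec4n, the lectin receptor Dectin-2, from 3.97 ± 0.520 to 87.9 ± 3.87 (4.48). Il1b, the cytokine interleukin-1 beta, rose from 0.704 ± 0.174 to 15.3 ± 0.410 CPM (4.43). Thbs1, the matrix protein thrombospondin-1, rose from 12.6 ± 0.211 to 192 ± 4.45 CPM (3.93), and the chemokine receptor gene Ccr1 from 17.9 ± 1.85 to 156 ± 3.0 (3.13). The deepest falls among such genes were those of Ltf, the granule protein lactoferrin, from 12.6 ± 0.522 to 0.391 ± 0.181 CPM (log2 fold change -5.00), and Chil3, the chitinase-like protein Ym1, from 11 ± 0.595 to 0.550 ± 0.115 (-4.28). Timp1, a metalloproteinase inhibitor, fell from 21.8 ± 0.708 to 1.33 ± 0.118 CPM (-4.03). Ngp, a neutrophil granule protein, fell from 15.8 ± 0.437 to 0.976 ± 0.377 CPM (-3.98), and Adra1a, an adrenergic receptor, from 40.6 ± 1.76 to 3.44 ± 0.173 (-3.56). Markers of neutrophils and their precursors, to which Ltf and Ngp belong, summed to 52.2 CPM in WT naive and 4.77 in WT TCM, and all 6 tested members fell (adjusted p = 7.3e-05, 0.0164 with an estimated correlation). Markers of stromal fibroblasts summed to 18.7 and 0.369 CPM, and all 6 tested members fell (adjusted p = 3.5e-05, 0.0158 with an estimated correlation).

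Of 15 genes of alternative activation, 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (median log2 fold change 0.47, adjusted p = 0.00072). Besides Mrc1, Il4ra, the receptor chain for interleukin-4, rose from 178 ± 2.98 to 491 ± 6.56 CPM (1.47), and Clec10a, a galactose-binding lectin, from 2.59 ± 0.257 to 19.3 ± 0.532 (2.90). The 3 that fell were Chil3, the chemokine gene Ccl24 and Pparg, a lipid-sensing nuclear receptor. Among 18 genes of classical inflammatory activation 8 rose and 4 fell, or 9 and 4 adjusted over the list alone. Nlrp3, the inflammasome sensor, rose from 53.6 ± 0.891 to 132 ± 3.21 CPM and the acute-phase gene Saa3 from 181 ± 6.55 to 443 ± 8.26. This list was called with the preset correlation (adjusted p = 0.020) and not with an estimated one (adjusted p = 0.116 with an estimated correlation), nor among genes of at least 50 counts (adjusted p = 0.107). Of 25 interferon-induced genes 22 fell and 2, Stat2 and Ddx58, rose, with the same counts adjusted over the list alone (median -0.43, adjusted p = 1.5e-10). Rsad2, the antiviral protein viperin, fell from 317 ± 4.54 to 209 ± 5.77 CPM, Ifit3 from 398 ± 2.17 to 267 ± 1.24 and Ifit2 from 592 ± 14.3 to 419 ± 4.85. Among 9 MHC class II genes 5 fell and 3 rose, both over all genes and adjusted over the list alone, and the list was not called (adjusted p = 0.112). H2-Eb1 fell from 34.9 ± 1.1 to 10.8 ± 1.27 CPM and H2-Ab1 from 71.7 ± 1.79 to 38.0 ± 2.59, each a chain of a different presenting molecule. H2-DMa and H2-DMb1, which load peptides onto such molecules, and H2-Ob, which restrains that loading, were the members that rose. Cd274, the checkpoint ligand PD-L1, fell from 77.9 ± 2.59 to 50.3 ± 1.52 CPM (log2 fold change -0.63, adjusted p = 9.6e-24).

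Glycolysis genes rose in 14 of 18 cases, the same number adjusted over the list alone (median log2 fold change 0.44, adjusted p = 1.9e-06). Slc16a3, the lactate exporter, rose from 37.9 ± 0.975 to 107 ± 2.24 CPM, and the pathway enzymes Pgk1 from 296 ± 3.53 to 514 ± 9.91 and Eno1 from 534 ± 9.59 to 905 ± 10.7. The 2 that fell were Hk3, a myeloid hexokinase, and Pfkfb3, a regulator of the pathway. Among 16 hypoxia-responsive genes 10 rose and 1, Ddit4, fell, or 11 and 1 adjusted over the list alone (adjusted p = 0.00072). Pdk1, which limits pyruvate entry into mitochondria, rose from 39.0 ± 1.26 to 88.7 ± 2.06 CPM. Cholesterol synthesis genes rose in 13 of 21 cases with 0 lower, the same counts adjusted over the list alone (median 0.17, adjusted p = 0.00058), among them Stard4 (0.58) and Fdft1 (0.58). Of 23 cell cycle genes 14 rose and 1, Pcna, fell, or 15 and 1 adjusted over the list alone (median 0.28, adjusted p = 0.00043), with the replication helicase genes Mcm2 (0.58) and Mcm3 (0.49) among them. All of these lists, and those of alternative activation and interferon, were also called with an estimated correlation, at adjusted p between 0.0161 and 0.0381. Respiratory chain genes were not called with camera. Of the 25 encoded in the nucleus 5 rose and 5 fell (adjusted p = 0.918), and of the 12 encoded in mitochondria 3 rose and 2 fell (adjusted p = 0.283, and adjusted p = 0.0139 as higher with the rotation test fry).

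The list of efferocytosis and complement was not called (8 of 17 higher, 4 lower, adjusted p = 0.143), with the receptor tyrosine kinase gene Axl higher (1.48) and the phagocytosis bridge Mfge8 lower (-1.40). Nor was that of lipid efflux (5 of 12 higher, 6 lower, or 6 and 6 adjusted over the list alone, adjusted p = 0.764), with Apoe higher (0.64) and its regulator Nr1h3 lower (-1.40). Where no second count is given for a list, the count adjusted over the list alone was the same. The matrix list had 7 of 20 genes higher and 12 lower (adjusted p = 0.222), and it holds Timp1, which fell with the fibroblast markers. Arg1, an arginine-degrading enzyme of alternatively activated macrophages, was at 1.37 ± 0.298 and 1.90 ± 0.229 CPM (log2 fold change 0.47, adjusted p = 0.066), and without WT naive replicate 1 it was called (0.64). Nos2, which makes nitric oxide, was at 0.561 ± 0.116 and 1.06 ± 0.224 CPM (adjusted p = 0.058). Il10, the anti-inflammatory cytokine, fell from 5.58 ± 0.0709 to 4.07 ± 0.454 CPM (log2 fold change -0.46, adjusted p = 0.011), a call lost without WT TCM replicate 1 (adjusted p = 0.0699). Timd4, a receptor for dying cells, lay at 0.0963 and 0.133 CPM, 6 and 7 counts per group (adjusted p = 0.702), and Ppargc1a, a regulator of mitochondrial biogenesis, had 1 to 5 counts per group and was not tested.

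TRAP1 KO TCM was compared with WT TCM to see what changed in macrophages under melanoma medium when the mitochondrial chaperone was missing. Arg1 (chromosome 10, 24915221 to 24927484) rose from 1.90 ± 0.229 to 22.8 ± 1.26 CPM (log2 fold change 3.59, SE 0.13, adjusted p = 2.5e-43). Apoe (chromosome 7, 19696109 to 19699188), the apolipoprotein of cholesterol export, fell from 9950 ± 97.6 to 2211 ± 51.4 CPM (-2.17, adjusted p = 1.6e-79). Every one of 23 cell cycle genes and 21 cholesterol synthesis genes fell, and 20 of 25 interferon-induced genes fell with 0 higher. Tgfbr2, the TGF-beta receptor, rose from 412 ± 4.59 to 1182 ± 12.5 CPM (1.52). Among 14078 genes tested, 2990 rose and 2954 fell, 401 and 385 of them at least 2-fold, and the median absolute log2 fold change of the called genes was 0.281.

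Of named genes with a mean of at least 5 CPM, the strongest rises besides Arg1 were those of Sema3c, a secreted guidance factor, from 0.482 ± 0.253 to 10.6 ± 1.47 CPM (log2 fold change 4.39), and Lilra6 (chromosome 7, 3908280 to 3915503), a leukocyte receptor, from 7.18 ± 0.445 to 92.9 ± 10.5 (3.69). Slpi, a protease inhibitor, rose from 2.05 ± 0.445 to 25.6 ± 1.12 CPM (3.66). Cd38, an enzyme that consumes NAD, rose from 2.52 ± 0.357 to 27.3 ± 1.59 CPM (3.43). The deepest falls among such genes after Trap1 itself were those of Rpl29, a ribosomal protein, from 178 ± 5.74 to 0.751 ± 0.144 CPM (-7.87), and Slc13a3, a dicarboxylate transporter, from 23.4 ± 0.390 to 0.676 ± 0.286 (-5.10). Rpl29 has processed pseudogenes, and how any reads shared with them were counted is not known. It was at 153 CPM in WT naive, 108 in JMJD3 WT TCM and 122 in JMJD3 cKO TCM. The predicted gene Gm8730, which the rule for names leaves out, rose in TRAP1 KO TCM from 3.58 ± 0.604 to 142 ± 8.25 CPM (5.29). The source of either change was not tested. Fblim1, an adaptor of cell adhesions, fell from 164 ± 7.23 to 16.2 ± 0.769 CPM (-3.34), and Padi4, which converts arginine in proteins to citrulline, from 10.3 ± 0.185 to 1.09 ± 0.366 (-3.22). Genes changed at least 2-fold were concentrated in 5 windows of 5 Mb. The densest lay on chromosome 14 from 50 to 55 Mb (18 of 56 genes tested, adjusted p = 3.4e-07, Fisher's exact test over 499 windows). The others were on chromosome 14 from 65 to 70 Mb (8 of 26), chromosome 1 from 190 to 195 Mb (10 of 32), chromosome 7 from 0 to 5 Mb (13 of 54) and chromosome 17 from 75 to 80 Mb (7 of 22). These windows hold Lilra6, Mmp14 and Atf3, and 56 of the 786 genes changed at least 2-fold. Outside them 2936 genes rose and 2874 fell.

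Cell cycle genes fell in 23 of 23 cases, the same adjusted over the list alone (median log2 fold change -0.99, adjusted p = 4.5e-16). Top2a, the topoisomerase of dividing cells, fell from 87.5 ± 1.67 to 32.5 ± 1.45 CPM, the proliferation marker Mki67 from 81.0 ± 2.13 to 31.6 ± 1.24 and the replication clamp Pcna from 331 ± 3.81 to 179 ± 2.27. All 21 cholesterol synthesis genes fell, also 21 adjusted over the list alone (median -0.76, adjusted p = 3.7e-15). Insig1, which senses sterols, fell from 99.8 ± 3.56 to 49.8 ± 2.87 CPM. Srebf2, the master regulator of the pathway, fell from 333 ± 9.29 to 231 ± 4.79 CPM and the sterol demethylase Cyp51 from 71.5 ± 1.90 to 35.7 ± 1.02. Genes of lipid efflux fell too, 10 of 12 with 0 higher, the same adjusted over the list alone (median -0.46, adjusted p = 3.7e-08), among them the cholesterol exporter of lysosomes Npc1 (-0.67) and the lipid droplet coat Plin2 (-0.48). Interferon-induced genes fell in 20 of 25 cases, the same number adjusted over the list alone (median -0.32, adjusted p = 4.4e-11). Rsad2 fell from 209 ± 5.77 to 123 ± 2.84 CPM, and the antiviral synthetase genes Oas3 from 659 ± 13.2 to 474 ± 6.36 and Oasl2 from 580 ± 1.79 to 445 ± 3.19. Alternative activation genes rose in 11 of 15 cases and fell in 3, the same adjusted over the list alone (median 0.57, adjusted p = 0.00019). Mrc1 rose from 2691 ± 45.5 to 3822 ± 31.1 CPM, the scavenger receptor Msr1 from 715 ± 12.1 to 1253 ± 22.5 and Il4ra from 491 ± 6.56 to 808 ± 11.2. Chil3, Pparg and the transglutaminase gene Tgm2 were the 3 that fell. These 5 lists were also called with an estimated correlation, at adjusted p between 0.00051 and 0.0185.

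MHC class I genes fell in 8 of 12 cases, also 8 adjusted over the list alone, with B2m, the light chain of the complex, from 3770 ± 52.0 to 3035 ± 26.8 CPM and the class I activator Nlrc5 lower (-0.52). The list was called with the preset correlation (adjusted p = 0.0024) and not with an estimated one (adjusted p = 0.0542 with an estimated correlation). Mitochondrially encoded respiratory chain genes rose in 9 of 12 cases with 0 lower, the same adjusted over the list alone. This call (adjusted p = 0.00011) was also lost (adjusted p = 0.171 with an estimated correlation). The complex I subunits mt-Nd2 and mt-Nd1 rose from 722 ± 13.5 to 1051 ± 9.79 CPM and from 1168 ± 24.4 to 1483 ± 19.5. Of the 25 nuclear-encoded respiratory chain genes 3 rose and 2 fell, or 1 and 1 adjusted over the list alone (adjusted p = 0.979). Stress response genes fell in 13 of 19 cases and rose in 5, the same adjusted over the list alone. The transcription factor gene Atf3 fell from 127 ± 4.99 to 70.7 ± 4.23 CPM and the mitochondrial folate enzyme Mthfd2 from 74.1 ± 2.75 to 46.3 ± 2.57. The call of this list (adjusted p = 0.024) was lost with an estimated correlation (adjusted p = 0.154 with an estimated correlation) and outside the 5 windows (adjusted p = 0.0675). Matrix and growth factor genes rose in 14 of 20 cases and fell in 4, or 14 and 5 adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.0909 with an estimated correlation). The plasminogen activator gene Plau rose from 397 ± 3.26 to 694 ± 6.02 CPM and the membrane metalloproteinase Mmp14 from 106 ± 6.55 to 198 ± 2.83. Fibroblast markers summed to 0.369 CPM in WT TCM and 8.01 CPM in TRAP1 KO TCM, with 5 of 6 higher (adjusted p = 0.00058, 0.0348 with an estimated correlation). Monocyte markers summed to 95.2 and 155 CPM, nearly all Ccr2, with 4 of 6 higher (adjusted p = 0.010, and adjusted p = 0.0812 with an estimated correlation).

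The MHC class II list was not called (5 of 9 higher, 2 lower, adjusted p = 0.0802), although Cd74 rose from 111 ± 3.54 to 200 ± 6.87 CPM and H2-Eb1 from 10.8 ± 1.27 to 28.2 ± 1.3. Classical activation genes went both ways (11 of 18 higher, 5 lower, adjusted p = 0.0675). The T cell chemokine Ccl5 fell from 662 ± 23.1 to 166 ± 3.76 CPM, and the neutrophil chemokine Cxcl2 rose from 12.8 ± 0.559 to 45.5 ± 1.49. Among H3K27 methylation genes 2 of 12 rose and 5 fell (adjusted p = 0.53), with the Polycomb cofactor Jarid2 from 53.3 ± 0.510 to 99.3 ± 2.47 CPM and the methyltransferase Ezh2 lower (-0.60). Glycolysis (7 of 18 higher, 5 lower) and hypoxia (5 of 16 higher, 4 lower, or 5 and 5 adjusted over the list alone) were not called (adjusted p = 0.53 and 0.987), and Vegfa fell from 109 ± 1.37 to 92.6 ± 3.71 CPM (-0.23). Mitochondrial chaperones and proteases had 5 of 15 genes higher and 4 lower, with the chaperone Hspa9 higher by 0.13 and the protease Yme1l1 by 0.20 on the log2 scale. The median (0.05), the mean (-0.67, with Trap1 in it) and the direction of the test (higher, adjusted p = 0.979) of this list differed in sign. Timd4 rose from 0.133 ± 0.231 to 2.35 ± 0.299 CPM, 7 counts against 178, a ratio of 17.4 with an exact 95% interval of 8.29 to 44.0. All 7 counts lay in WT TCM replicate 2, and without that library Timd4 was at least 26.9-fold higher, with 3 counts over the group as the limit. Cd274 fell slightly, from 50.3 ± 1.52 to 42.4 ± 1.25 CPM (-0.25, adjusted p = 1.5e-06), and Il10 did not pass the test (-0.19, adjusted p = 0.35). Nos2, at 1.06 ± 0.224 and 0.541 ± 0.250 CPM, was called (-0.96, adjusted p = 0.030), but not with DESeq2 (0.0699) nor without WT TCM replicate 2 or 3 (0.0526, 0.148) or TRAP1 KO TCM replicate 2 or 3 (0.135, 0.0649).

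JMJD3 cKO TCM was compared with JMJD3 WT TCM to see what changed when the H3K27 demethylase was targeted, with the reservation that Kdm6b itself was not lower in the libraries labelled JMJD3 cKO. Interferon-induced genes fell in 25 of 25 cases, led by Rsad2, from 3399 ± 126 to 1204 ± 30.8 CPM (log2 fold change -1.50, SE 0.03, adjusted p = 2.5e-37). The call of the interferon list was lost when the correlation between genes was estimated (adjusted p = 0.181 with an estimated correlation). Cd274 (chromosome 19, 29367455 to 29388095), the checkpoint ligand PD-L1, fell from 537 ± 12.2 to 294 ± 4.13 CPM (-0.87, adjusted p = 8.4e-28). Nos2 fell from 34.5 ± 1.45 to 10.7 ± 0.265 CPM (-1.68), Il10 from 15.9 ± 0.886 to 8.49 ± 0.145 (-0.91), and 22 of 23 cell cycle genes rose. Arg1 did not differ detectably, at 9.07 ± 1.24 and 9.05 ± 0.884 CPM (log2 fold change -0.00, SE 0.12, adjusted p = 0.98). Among 13476 genes tested 2326 rose and 2402 fell, 113 and 185 of them at least 2-fold, and the median absolute log2 fold change of the called genes was 0.279.

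With a mean of at least 5 CPM, the named genes that rose most were Lyz1, a lysozyme, from 2.79 ± 0.0880 to 11 ± 1.13 CPM (log2 fold change 1.97), and Rrm2, which makes the building blocks of DNA, from 3.02 ± 0.488 to 9.05 ± 0.0748 (1.58). Acap1 (chromosome 11, 69881567 to 69895539, close to Kdm6b), a regulator of membrane traffic, rose from 6.29 ± 0.447 to 16.4 ± 1.35 CPM (1.38). Clspn, a replication checkpoint gene, rose by 1.19 and the macrophage elastase Mmp12 by 1.15, from 154 ± 8.25 to 342 ± 5.97 CPM. The deepest falls at this level were those of Cxcl11, an interferon-induced chemokine, from 32.0 ± 1.05 to 5.06 ± 0.400 CPM (-2.66), and Lipg, the endothelial lipase, from 137 ± 5.26 to 22.8 ± 0.414 (-2.58). The transcription factor gene Lhx2 fell from 21.6 ± 1.05 to 3.62 ± 0.705 CPM (-2.56). Clic5, a chloride channel protein, fell from 8.53 ± 1.29 to 1.97 ± 0.366 CPM (-2.11) and Pira2, a paired receptor, from 21.6 ± 2.69 to 5.15 ± 0.280 (-2.07). Nlrp1a, an inflammasome gene near Kdm6b, had 3 counts in the libraries labelled JMJD3 cKO against 237, a ratio of 102 with an exact 95% interval of 34.6 to 500.2. The neighbouring pseudogene Nlrp1c-ps had 0 against 404, at least 175-fold lower with 3 counts over the group as the limit.

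All 25 interferon-induced genes tested fell, also 25 adjusted over the list alone (median -0.65, adjusted p = 1.7e-20, and adjusted p = 0.181 with an estimated correlation). Ifit2 fell from 3805 ± 81.8 to 2024 ± 66.1 CPM and Mx1, which blocks viral replication, from 1115 ± 20.7 to 612 ± 12.8. MHC class I genes fell in 11 of 12 cases, with the peptide trimmer Erap1 higher, the same adjusted over the list alone (adjusted p = 7.1e-05, and adjusted p = 0.181 with an estimated correlation). The peptide transporter gene Tap1 fell from 695 ± 17.8 to 515 ± 1.85 CPM, and the class I activator Nlrc5 fell as well (-0.49). Classical activation genes fell in 10 of 16 cases and rose in 2, Ccl3 and Nlrp3, or 11 and 2 adjusted over the list alone (adjusted p = 0.00039, and adjusted p = 0.181 with an estimated correlation). Acod1, the itaconate synthase, fell from 231 ± 9.06 to 70.9 ± 1.38 CPM, and Cd86, a T cell costimulator, from 75.9 ± 0.814 to 45.3 ± 2.25. Cell cycle genes rose in 22 of 23 cases, with Pcna lower (-0.32), and the same adjusted over the list alone (median 0.82, adjusted p = 2.2e-10). This was the list of the JMJD3 comparison that was also called with an estimated correlation (adjusted p = 0.0406). Top2a rose from 16.8 ± 0.307 to 34.8 ± 0.337 CPM and Mki67 from 18.4 ± 1.60 to 34.2 ± 2.73. Neutrophil markers summed to 24.0 and 40.6 CPM, with 4 of 5 higher (adjusted p = 0.019, and adjusted p = 0.149 with an estimated correlation). Immediate-early and heat-shock genes fell in 6 of 9 cases (adjusted p = 0.0060, and adjusted p = 0.149 with an estimated correlation).

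TCA cycle genes rose in 11 of 17 cases with 0 lower, or 13 adjusted over the list alone, with Idh3a from 19.4 ± 0.715 to 26.1 ± 0.758 CPM and Suclg2 from 10.4 ± 0.0896 to 14.9 ± 1.28. Cholesterol synthesis genes rose in 14 of 21 cases with 0 lower, the same adjusted over the list alone, among them Sqle (0.46), Stard4 (0.48) and Cyp51 (0.37). The calls of both lists (adjusted p = 0.00023 and 0.00043) were lost (adjusted p = 0.181 for each with an estimated correlation). Glycolysis genes fell in 13 of 18 cases with 0 higher, or 13 and 1 adjusted over the list alone (adjusted p = 0.00039, and adjusted p = 0.304 with an estimated correlation). Hypoxia-responsive genes fell in 9 of 16 with Car9 higher, the same adjusted over the list alone (adjusted p = 0.010, and adjusted p = 0.291 with an estimated correlation). Hk3 fell from 1087 ± 30.7 to 834 ± 5.6 CPM, Slc16a3 from 166 ± 6.57 to 124 ± 2.20, Vegfa from 140 ± 5.23 to 99.2 ± 2.32 and the oxygen sensor gene Egln3 from 9.25 ± 0.485 to 3.59 ± 0.834. Stress response genes fell in 11 of 18 cases with Psat1 and Shmt2 higher, the same adjusted over the list alone (adjusted p = 0.0039, and adjusted p = 0.289 with an estimated correlation). Atf3 fell from 555 ± 16.9 to 328 ± 3.0 CPM and Ddit3, a death-promoting factor, from 166 ± 10.6 to 102 ± 4.94. Lipid efflux genes fell in 7 of 13 cases with Apoe higher, the same adjusted over the list alone (adjusted p = 0.0077, and adjusted p = 0.221 with an estimated correlation). The sterol exporter gene Abcg1 fell from 530 ± 6.01 to 350 ± 6.63 CPM. Mitochondrial chaperones were not called (8 of 15 higher, 1 lower, adjusted p = 0.0507), with Hspd1 from 63.0 ± 4.84 to 87.4 ± 4.09 CPM, Hspe1 higher by 0.41 and Trap1 by 0.22 on the log2 scale (adjusted p = 0.00051). Without JMJD3 WT TCM replicate 2 or JMJD3 cKO TCM replicate 1 this list was called (0.0429 and 0.0375).

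Immunosuppressive mediators went both ways and were not called (7 of 16 higher, 6 lower, or 7 and 7 adjusted over the list alone, adjusted p = 0.536). Il1rn, the interleukin-1 receptor antagonist, fell from 886 ± 44.6 to 363 ± 5.46 CPM (-1.29), and Lilrb4a, an inhibitory receptor, by 0.52 on the log2 scale from 882 ± 22.2 to 617 ± 13.4 CPM. Alternative activation genes were not called either (4 of 15 higher, 6 lower, adjusted p = 0.536), with Mrc1 from 880 ± 16.5 to 1072 ± 15 CPM and Il4ra from 654 ± 5.68 to 512 ± 7.48. Among matrix genes Thbs1 fell from 859 ± 27.7 to 381 ± 10.6 CPM and Mmp14 from 64.1 ± 3.49 to 32.3 ± 1.95 (6 of 20 higher, 7 lower, or 6 and 10 adjusted over the list alone, adjusted p = 0.536). H3K27 methylation genes had 4 of 12 higher and 4 lower (adjusted p = 0.983), with Kdm6a, the related demethylase, at 65.3 ± 1.82 and 56.6 ± 0.701 CPM (-0.21, adjusted p = 0.00030). Efferocytosis genes had 9 of 16 higher and 5 lower (adjusted p = 0.536), with Mfge8 higher (0.85) and Axl lower (-0.51).

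**Figure D2:**
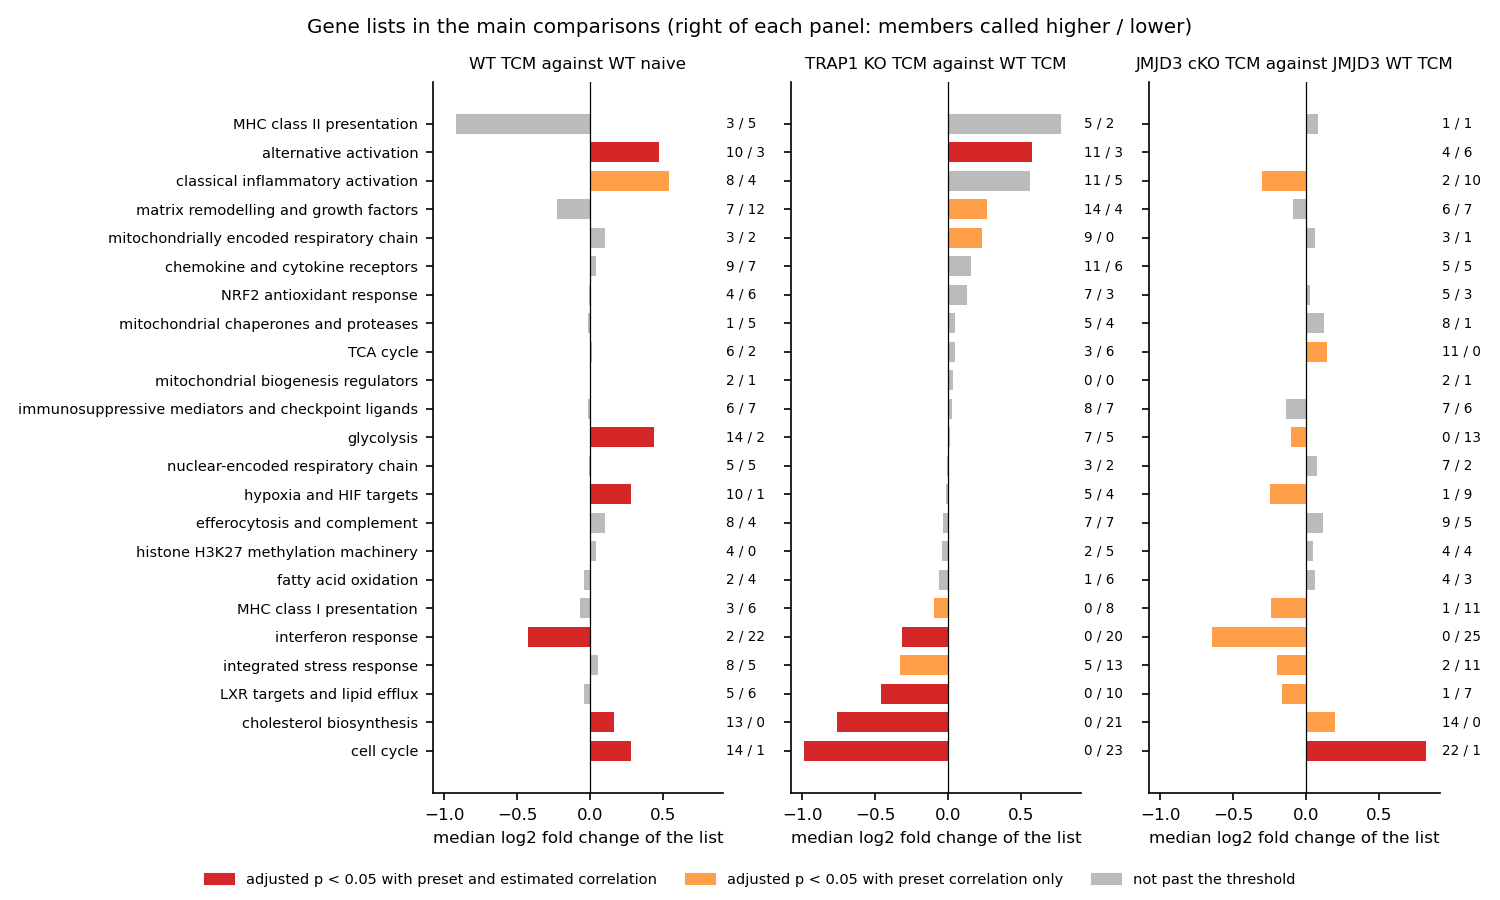
Median log2 fold change (x axis) of the 23 gene lists (y axis) in the 3 main comparisons, with the numbers of higher and lower members beside each bar, red for lists called with both correlations, orange for the preset one alone and grey for lists not called. Cell cycle genes had a median of 0.28 with TCM, -0.99 without TRAP1 and 0.82 in the libraries labelled JMJD3 cKO.

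JMJD3 WT TCM was set beside WT TCM to measure how far the wild-type cells of both sets stood apart under the same medium. Rsad2 was at 3609 CPM in JMJD3 WT TCM and 202 in WT TCM (log2 fold change 4.16), Ifit2 at 4040 and 405 (3.32), Cd274 at 570 and 48.7 (3.55) and Nos2 at 36.6 and 1.02 (5.18). Top2a was at 17.9 and 84.7 CPM (-2.25), Mrc1 at 934 and 2603 (-1.48) and the mitochondrial gene mt-Nd1 at 538 and 1130 (-1.07). All 25 interferon-induced genes (median 2.49, adjusted p = 5.4e-22) and all 12 MHC class I genes were higher, 22 of 23 cell cycle genes were lower with 1 higher, and 20 of 21 cholesterol synthesis genes were lower. These 4 lists were also called with an estimated correlation, at adjusted p between 0.00036 and 0.0018. Monocyte markers were higher in 5 of 6 cases (adjusted p = 0.0045, 0.0265 with an estimated correlation) and neutrophil markers in 6 of 6 (adjusted p = 0.013, and adjusted p = 0.0523 with an estimated correlation), with sums of 214 and 24.0 CPM in JMJD3 WT TCM against 95.2 and 4.77 in WT TCM. Altogether 4366 genes were higher and 4554 lower among 14545 tested, 1277 and 831 of them at least 2-fold. Line, sex and any difference in handling cannot be told apart here.

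The difference between the genotype effects, each taken within its own set, tested whether loss of TRAP1 and targeting of JMJD3 acted alike. Among the 23 gene lists, cell cycle genes parted the most, with all 23 lower in the difference (median -2.12, adjusted p = 6.6e-20, 1.8e-05 with an estimated correlation). All 21 cholesterol synthesis genes were lower as well (median -0.97, adjusted p = 9.1e-16, 3.9e-05 with an estimated correlation). Alternative activation genes were higher in the difference in 11 of 16 cases and lower in 3 (median 0.75, adjusted p = 0.00017, 0.0071 with an estimated correlation). Interferon-induced genes fell with both genotypes, in the JMJD3 comparison with the preset correlation alone (adjusted p = 0.181 with an estimated correlation), and less without TRAP1 (18 higher and 4 lower in the difference, or 19 and 5 adjusted over the list alone, adjusted p = 1.2e-06, and adjusted p = 0.0744 with an estimated correlation). Matrix genes were higher in the difference in 13 of 20 cases and lower in 3 (adjusted p = 0.0012, 0.0166 with an estimated correlation). Monocyte markers were higher in 5 of 6 cases and immediate-early and heat-shock genes in 6 of 9 (adjusted p = 0.0046, 0.0385 with an estimated correlation, for each). Fibroblast markers were higher in 2 of 6 (adjusted p = 0.013, 0.0404 with an estimated correlation), with 0 lower in these 3 lists. In all, 2680 genes were higher and 2839 lower in the difference among 14545 tested.

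**Figure D3:**
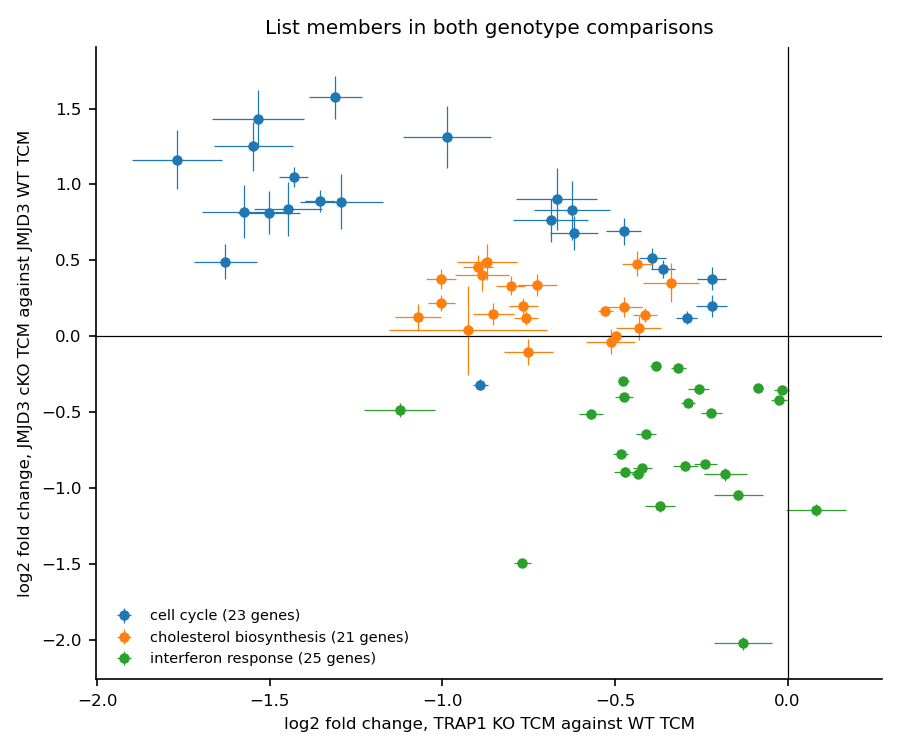
Log2 fold change without TRAP1 (x axis) against that in the libraries labelled JMJD3 cKO (y axis) for genes of the cell cycle, cholesterol synthesis and interferon lists, with bars of 1 SE. Of 23 cell cycle genes 22 lay lower without TRAP1 and higher in the other comparison, and of 25 interferon-induced genes 24 lay lower in both.

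Across 13216 genes tested in both genotype comparisons, which share no library, the fold changes were hardly related (Pearson r = -0.03, Spearman rho = -0.03, across genes, which are not independent replicates). Genes called in both exceeded independent lists in all 4 pairs of directions, opposite ones included. The expected numbers treat every gene as equally easy to call, while precisely measured genes are called more readily in both comparisons. The excess by itself is therefore no evidence of shared or opposed regulation. Lower in both were 735 against 514.4 (adjusted p = 1.9e-31, raw p = 4.8e-32, one-sided Fisher's exact test over 4 pairs), among them Ifit1bl1, Mid1, Pou3f1, Tpx2 and Scd1, the stearoyl desaturase (-2.70 and -0.86). Lower without TRAP1 and higher with the other genotype were 698 against 511.9 (adjusted p = 2.7e-23, raw p = 1.3e-23, Fisher's exact test), among them Rrm2 (-1.31 and 1.58), Clspn, Foxm1, Top2a (-1.43 and 1.05) and Stmn1, all genes of dividing cells. Tpx2, another such gene, was lower in both (-1.03 and -0.91). Higher in both were 637 against 494.9 (adjusted p = 7.8e-15, raw p = 5.9e-15, Fisher's exact test), among them Cd38 (3.43 and 0.68), the gelatinase gene Mmp9, Lama3, Igfbp4 and Pf4. Higher without TRAP1 and lower with the other genotype were 612 against 497.2 (adjusted p = 2.1e-10, raw p = 2.1e-10, Fisher's exact test), among them the chemokine genes Ccl8 (1.64 and -1.15) and Ccl12, the scavenger receptor Marco (1.13 and -1.32), Ednrb and Ch25h. The 354 genes lower without TRAP1 by at least 2-fold had a median of 0.17 in the JMJD3 comparison, with 108 higher and 54 lower. Over 4 such sets they were not called with the preset correlation (camera p = 0.027, adjusted p = 0.109), and they were with an estimated one (adjusted p = 0.0387 with an estimated correlation).

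The effects of TCM and of TRAP1 loss were set against each other gene by gene. The series holds no TRAP1 knockout library without TCM. A changed response to the medium therefore cannot be told from a difference that knockout cells have without it. Both effects use the WT TCM libraries. Simulated groups without any change gave a mean Pearson r of -0.56 (-0.58 to -0.55 in 20 simulations) through these libraries alone. The observed r was -0.18 (Spearman rho = -0.08, 14078 genes), and it was 0.03 among genes of at least 50 counts. The simulated r holds noise alone, so it is no reference for an r that also holds real changes. The covariance was -0.0646 against -0.0175 in the simulations, a difference of -0.0470. Genes higher with TCM and higher again without TRAP1 numbered 988 (645.7 for independent lists), among them Clec4n (4.48 and 2.17), Clec10a (2.90 and 1.55), Cxcl2, Ednrb and Arhgef40. Higher with TCM and lower without TRAP1 were 855 (637.9), among them the lipid desaturases Scd1 (1.11 and -2.70) and Fads2 (1.57 and -2.30), Mid1 and Rnase6. Lower and then higher were 751 (615.5), among them Cd38 (-1.78 and 3.43), Ly6a, Ccl8, Gstp1 and Inka2, and lower in both were 808 (608.1), among them Mfge8 (-1.40 and -1.26), Pou3f1, Nanos1 and Ifit1bl1. Arhgef40 and Rnase6 lie in the enriched window of chromosome 14. The simulations gave at most 1 gene called in opposite directions and 0 in the same one. No gene changed in them, so these counts are no reference for the shared calls. Nor are the numbers for independent lists, which treat every gene as equally easy to call.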

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

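The effects of the 2 genotypes parted for genes of the cell cycle and of cholesterol synthesis, the lists called in opposite directions in the 2 comparisons with the preset correlation, and both differences were tested as planned. The rise of cholesterol synthesis genes in the JMJD3 comparison was lost with an estimated one (adjusted p = 0.181 with an estimated correlation). For 23 cell cycle genes the median of the difference between the effects was -2.12 on the log2 scale, with all 23 genes lower in it (adjusted p = 6.6e-20, 1.8e-05 with an estimated correlation). The topoisomerase Top2a fell from 87.5 to 32.5 CPM without TRAP1 and rose from 16.8 to 34.8 CPM in the libraries labelled JMJD3 cKO, and the proliferation marker Mki67 fell from 81.0 to 31.6 and rose from 18.4 to 34.2 CPM. For 21 cholesterol synthesis genes the median difference was -0.97, again with all 21 lower (adjusted p = 9.1e-16, 3.9e-05 with an estimated correlation). Insig1, which senses sterols, fell from 99.8 to 49.8 CPM without TRAP1 and rose from 49.6 to 57.8 CPM with the other genotype, and Srebf2 fell from 333 to 231 and rose from 216 to 242 CPM. The controls of the 2 comparisons began at different levels, since Top2a lay at 87.5 CPM in WT TCM and 16.8 CPM in JMJD3 WT TCM, and the line, the sex of the cells and the starting level cannot be told apart as sources of the difference.

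Single libraries lay apart from the rest of their group for 7 of 81 values tested in TRAP1 KO TCM with Dixon's test, which was not run on the groups of 3. The values were those of the named genes, the total count and the mitochondrial share, and all 7 belonged to genes. Chance marks about 1 in 20 such groups, which is about 4 of 81. In replicate 4, Trap1 had 0 counts (0 CPM against 0.0475 to 0.0535 in the other 3, which is 1 count each). In that library Spp1, the secreted protein osteopontin, was at 2954 CPM (others 2796 to 2807), the complex I gene mt-Nd1 at 1453 (1414 to 1420), Jarid2, a partner of the H3K27 methyltransferase, at 98.97 (94.02 to 94.71) and Srebf2 at 229.2 (219.8 to 220.4). In replicate 2, the scavenger receptor gene Msr1 was at 1172 CPM (others 1214 to 1221) and mt-Nd2 at 995.8 (1015 to 1018). All 7 genes were called in TRAP1 KO TCM against WT TCM in the same direction with either of these libraries left out, as for Spp1 (log2 fold change 0.73 without replicate 4) and Msr1 (0.82 without replicate 2).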

How the results depend on the processing

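Leaving out the genes of the 5 enriched chromosome windows was chosen only after the data were seen. Of 240 results for named genes 233 were called, and 10 crossed the threshold under at least 1 alternative, with 0 reversed. Sirt3 and Tfb1m, both higher with TCM, were not called without WT naive replicate 2 (adjusted p = 0.0662 and 0.146), nor without WT TCM replicate 2 for Sirt3 (0.0539) and WT TCM replicate 1 for Tfb1m (0.170). Il10 was not called without WT TCM replicate 1 (adjusted p = 0.0699), and Arg1 was called with TCM without WT naive replicate 1 (adjusted p = 0.0270). Without TRAP1, Nos2 was not called with DESeq2 (adjusted p = 0.0699) or without WT TCM replicate 2 or 3 or TRAP1 KO TCM replicate 2 or 3 (adjusted p between 0.0526 and 0.148). Sdhd was not called with DESeq2 (adjusted p = 0.0539) or without WT TCM replicate 1 (0.0988), nor Ndufs7 without WT TCM replicate 3 (0.0724). In the JMJD3 comparison Tfb2m was not called with DESeq2 (adjusted p = 0.104) or without JMJD3 WT TCM replicate 2 or 3 or JMJD3 cKO TCM replicate 2 (adjusted p between 0.0643 and 0.185). Ciita was not called without JMJD3 WT TCM replicate 2 (adjusted p = 0.0618), and mt-Nd3 without JMJD3 WT TCM replicate 1 (0.0878).

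Of 69 results for gene lists 26 were called, and 40 crossed the threshold or reversed under at least 1 alternative. With a correlation estimated per list, 1 call was lost with TCM (classical activation), 4 without TRAP1 (MHC class I, mitochondrially encoded respiratory chain, integrated stress response, matrix) and 9 in the JMJD3 comparison, interferon and glycolysis genes among them. The rotation test fry, which asks another question than camera (any change of the list), called 10, 6 and 7 further lists in the 3 comparisons. It also reversed 3 that the preset correlation had not called, which were matrix genes with TCM (adjusted p = 1.8e-05), mitochondrial chaperones without TRAP1 (adjusted p = 3.0e-06) and efferocytosis genes in the JMJD3 comparison (adjusted p = 0.0483). The cause was not tested, and the chaperone list holds Trap1 itself, without which fry was not run. Among genes of at least 50 counts, MHC class II genes were called as lower with TCM (adjusted p = 0.0392) and classical activation was not called (adjusted p = 0.107). Without WT TCM replicate 1, MHC class II genes were called as higher in TRAP1 KO TCM (adjusted p = 0.0456). Without JMJD3 WT TCM replicate 2, nuclear respiratory chain genes (adjusted p = 0.0373) and mitochondrial chaperones (0.0429) were called as higher, the latter also without JMJD3 cKO TCM replicate 1 (0.0375). Without the enriched windows the integrated stress response, which loses Atf3 there, was not called with the TRAP1 comparison (adjusted p = 0.0675).

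Counts of called genes stayed within 1.5 times the reported ones under other scaling, filters, tests, sets of libraries and left-out replicates. A 2-fold minimum left 339 higher and 403 lower with TCM, 401 and 385 without TRAP1, 113 and 185 in the JMJD3 comparison, 1277 and 831 between the wild-type sets and 497 and 570 in the difference, by its own construction. Each replicate left out in turn gave 2767 to 2839 higher and 2603 to 2669 lower with TCM, 2604 to 2832 and 2682 to 2823 without TRAP1, 1892 to 2115 and 2116 to 2320 in the JMJD3 comparison, 4088 to 4206 and 4335 to 4444 between the wild-type sets and 2457 to 2593 and 2674 to 2822 in the difference. Which direction held more genes depended on the scaling, the filter, the test and the libraries in the fit. Under upper quartile scaling 2884 were higher and 3037 lower with TCM, 2841 and 3061 without TRAP1, and 2718 and 2113 in the JMJD3 comparison. Without TRAP1 they were 2486 and 2615 with DESeq2, and 2817 and 3009 with the 2 groups alone in the fit. Without a count filter they were 2739 and 2876 with TCM, and 2482 and 2040 in the JMJD3 comparison. At an adjusted p under 0.01 the genes higher with both genotypes were 405, and those lower with TCM and higher without TRAP1 were 482, fewer by construction. The correlation of the TCM and TRAP1 effects was 0.0327 among genes of at least 50 counts, reversed in sign, and -0.25 to -0.17 with 1 replicate left out. That of the 2 genotype effects lay between -0.04 and -0.02 under the alternatives named. With genes changed by more than 8-fold left out, the 2 correlations were -0.07 and -0.08. Outside the enriched windows it was -0.04, with 630 genes higher in both and 718 lower in both.

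Libraries with the same replicate number were no more alike across groups than others (correlations of -0.10 to 0.06), so no pairing was used. The number as a block gave 3040 higher and 2887 lower with TCM, 2791 and 2786 without TRAP1, and 2246 and 2333 in the JMJD3 comparison, and changed the call of 0 named genes and 0 lists. Tests on FPKM or TPM were intended and not run, since the tables hold counts alone. Depth limited the genes near 0, such as Ppargc1a with 1 to 5 counts per group, which was not tested.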

Other observations

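The tests of a strain variant, of Kdm6b and the Nlrp1 genes, of a granulocyte source and of a lower share of all other cells were chosen only after the results were seen. Several lists that were not called held genes that changed strongly in both directions. Among 19 chemokine and cytokine receptors, 9 were higher and 7 lower with TCM (adjusted p = 0.343) and 11 and 6 without TRAP1 (adjusted p = 0.0951). Tgfbr1, 1 chain of the TGF-beta receptor, fell from 204 ± 4.65 to 110 ± 4.67 CPM with TCM and to 79.0 ± 3.17 without TRAP1, while its partner Tgfbr2 rose from 260 ± 2.96 to 412 ± 4.59 and to 1182 ± 12.5. Csf3r, the receptor for G-CSF, rose without TRAP1 (0.57) and fell in the libraries labelled JMJD3 cKO (-0.71), where 5 receptors were higher and 5 lower, or 5 and 7 adjusted over the list alone (adjusted p = 0.780). Of 16 immunosuppressive mediators and checkpoint ligands 6 were higher and 7 lower with TCM (adjusted p = 0.913) and 8 and 7 without TRAP1 (adjusted p = 0.933). Spp1, the secreted protein osteopontin, rose with TCM (0.30) and from 1758 ± 21.0 to 2950 ± 81.6 CPM without TRAP1, and Gpnmb fell from 8242 ± 98.6 to 4860 ± 71.5 and to 3176 ± 31.5 CPM. The checkpoint ligand gene Vsir rose with TCM (0.70), Trem2 fell (-0.47), and Havcr2, which encodes TIM-3, fell without TRAP1 (-0.85).

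Of 16 antioxidant genes under NRF2 control 7 were higher and 3 lower without TRAP1 (adjusted p = 0.0951), with Gclm, which makes glutathione, from 40.8 ± 0.850 to 63.4 ± 4.27 CPM and Txnrd1 from 127 ± 3.11 to 162 ± 3.98. Txnrd1 also rose in the libraries labelled JMJD3 cKO (0.38), where 5 of 15 such genes were higher and 3 lower (adjusted p = 0.536). Of 16 genes of fatty acid oxidation 6 fell and 1 rose without TRAP1 (adjusted p = 0.0712), and the carnitine carrier Slc25a20 fell from 29.9 ± 0.976 to 17.3 ± 1.82 CPM. Of 17 TCA cycle genes 6 were higher and 2 lower with TCM (adjusted p = 0.714), and 3 and 6 without TRAP1 (adjusted p = 0.979). MHC class I genes were higher in 3 and lower in 6 of 12 cases with TCM, or 3 and 7 adjusted over the list alone (adjusted p = 0.222).

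Lyz2, the lysozyme of macrophages, was the most abundant marker in each of the 5 groups, at 7978 CPM in WT naive, 17940 in WT TCM and 17290 in TRAP1 KO TCM. Monocyte markers summed to 95.2 CPM in WT TCM and 155 in TRAP1 KO TCM, most of it the chemokine receptor gene Ccr2 (92.0 and 147 CPM). B cell markers summed to 6.26 CPM in WT naive, 7.55 in WT TCM and 19.2 in TRAP1 KO TCM, most of it Cd79b (3.26, 3.23 and 3.09 CPM) and Ighm, the heavy chain of IgM (2.01, 3.82 and 15.2 CPM). Melanoma markers summed to 83.8 CPM in WT naive and 84.9 in WT TCM, and Mitf, which macrophages also express, held 83.5 and 84.5 of these. Stromal fibroblast markers summed to 18.7, 0.369 and 8.01 CPM in WT naive, WT TCM and TRAP1 KO TCM. Markers of T and NK cells summed to 0.530 to 1.97 CPM over the 5 groups, those of mast cells to 0.252 to 2.12 and those of red cell precursors to 0.490 to 0.654.

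Chance as the source of the counts of called genes was examined with other splits of the same libraries. For TRAP1 KO TCM against WT TCM 1 of 35 splits called as many genes as the real one, 5944 against at most 68 in the others. For the difference between the genotype effects it was 1 of 100 splits drawn from 700, 5519 against at most 2234. The split with 2234 kept 1 of the 2 sets at its real grouping. Both shares lie under 0.05, which argues against a random assignment of these libraries. Other splits mix the groups and so call few genes, and replicates may share an animal or a culture. Chance differences between animals or cultures are therefore not covered. WT TCM against WT naive (5938 against 0), JMJD3 cKO TCM against JMJD3 WT TCM (4728 against 1) and the 2 wild-type sets (8920 against 0) each have 10 splits with 1 as large, and 10 splits are too few for a share under 0.05.

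Genes changed at least 2-fold without TRAP1 lay together in 5 windows that hold Lilra6, Mmp14, Atf3, Arhgef40 and Rnase6, where 1.9% of 1000 random orders of the genes gave any such window and at most 2. With 1 gene kept per symbol stem 3 windows were left, and in the densest 14 of 46 stems held a changed gene. The gene kept was a changed one wherever the stem had one, which favours such windows, and related genes can differ in stem. Families of neighbouring related genes therefore stay open as a cause. Without pseudogenes and predicted genes 1 window was left, with 16 of 50 genes changed, so those rows alone are not the whole pattern. Named genes that may share reads with them, or with related genes, stayed in this test. It therefore cannot decide on shared reads as a cause. A strain or donor variant, a difference in genetic background between knockout and control cells, cannot be told apart from a response of these neighbouring genes to the loss of TRAP1, since the 5 windows (0 in WT TCM against WT naive, 2 in the JMJD3 comparison, 6 between the wild-type sets) are the pattern itself and none lies on chromosome 16 with Trap1. Shared reads also stay open because pseudogenes made up 13.9% of the 202 genes changed at least 4-fold and 6.1% of those tested (Fisher's exact test, p = 3.6e-05). Besides, 4 of the 5 windows were not enriched without pseudogenes and predicted genes. A variant as the source of the fall of Rpl29 from 178 to 0.751 CPM was not tested.

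In the libraries labelled JMJD3 cKO, Kdm6b was not lower, and Nlrp1a, 1.68 Mb away, and its neighbour Nlrp1c-ps fell to 3 counts from 237 and to 0 from 404. Loss of the whole Kdm6b transcript in most cells is argued against by its log2 fold change of 0.035 (95% interval -0.16 to 0.23). A shift of reads to Nlrp1b is argued against too, since Nlrp1b changed by -9.40 CPM while the other 2 lost 12.97 CPM. How reads shared among the 3 Nlrp1 genes were counted is not known, so shared reads in other forms stay open. A strain or donor variant linked to Kdm6b may lie behind the loss of Nlrp1a and cannot be told apart from other sources here, since, with these 2 genes left out, 3 of 115 genes within 5 Mb changed at least 2-fold and 293 of 13358 elsewhere (one-sided Fisher's exact test, p = 0.465). So wide a region can dilute a narrower cluster, and a narrower one was not tested. Among the 3 were Acap1 (log2 fold change 1.38) and Mgl2 (-1.94), both between Kdm6b and Nlrp1a. Clec10a, next to Mgl2, was not called (0.16). A deletion of part of Kdm6b that leaves most of its transcript stays open, as do the labels, and the 3 Nlrp1 genes were lower in TRAP1 KO TCM as well (Nlrp1a -0.97, Nlrp1b -0.91, Nlrp1c-ps -1.46).

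Granulocyte genes such as Ltf, Ngp and S100a9 and fibroblast genes such as Col1a1 and Col1a2 were lower in WT TCM than in WT naive, and 0 of the 12 markers tested belong to another list. A single granulocyte source at another share stays open, since 1 of 6 markers, Ltf, had a ratio (0.0307) whose 95% counting interval (0.0186 to 0.0477) lay wholly over 2-fold from the 0.107 of the others, and Ltf is also the gene picked for the deepest fall. A single fibroblast source cannot be told apart from other sources, since the 6 fibroblast markers had 0 to 6 counts each in WT TCM (ratios to WT naive of 0 to 0.0685), and the test, in which 0 of 6 markers had such an interval, was made on TRAP1 KO TCM against WT naive. A lower share of every other cell type cannot be told apart from separate changes. The medians of -3.43 and -5.75 (-5.38 with genes at 0 counts at their bound) differed by 2.32 with an SE of 1.29 (1.95 at the bound). Other marker lists went both ways from WT naive to WT TCM. Sums fell for mast cells (2.12 to 0.375 CPM), T and NK cells (1.19 to 0.65) and dendritic cells (4.45 to 2.68). Of 6 monocyte markers 4 fell and 0 rose, with Ccr2 at 90.1 and 92.0 CPM. Red cell markers (0.554 and 0.635 CPM) and B cell markers (6.26 and 7.55 CPM) were not lower in sum. The B cell sum rose through Ighm (2.01 and 3.82), with Cd79b at 3.26 and 3.23, which counts against a lower share if these genes come from B cells. A response of the cells to the medium stays open, and the labels name no sort that would remove other cells.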
